A study of Homo sapiens with 4 samples.

How the data were processed

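Single-cell RNA-seq was performed on 4 samples, 2 libraries of human striatal organoids and 2 of striato-nigral circuitoids, taken to be at day 80 as the titles state. The samples were grouped by their titles. Per the submitters' processing notes, Cell Ranger 3.1 and R 4.1.1 were used with GRCh38 (hg38). The role of each tool, the annotation version, the filters and the use of strand are not given in the sources used here. Per the labels, each group's deposited lists belong to a raw matrix that both libraries of the group share. The lists hold barcode names and gene names with no value beside them. All 4 deposited lists were used, and 0 columns were left unmapped to a group or to all samples.

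Matrix values were not analysed here. The comparisons planned before the data were examined that need counts were therefore not run: cells kept after filtering, genes differing between circuitoids and organoids, and shares of cell classes. Depth per library, the number of cells and doublets are likewise not reported. Since 1 barcode list stands for 2 libraries, spread between libraries was not obtained, and leaving out 1 library was not possible. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only. Free RNA in droplets enters a raw list of barcodes, which is why an entry was not treated as a cell.

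Barcodes were read as 16-base sequences without the suffix. Every split from base 4 to base 12 was tried, and the split after base 7 gave the smallest number of combinations of first and second parts. A second part was called in use where at least 20% of its combinations were listed for organoids, with 10% and 30% as alternatives and the circuitoid list as another. Shared barcodes were compared with the product of the list sizes divided by the number of combinations. The ratio's SD came from 100 bootstrap draws of second parts with a fixed seed. On simulated lists with planted ratios of 1 and 1.5 among second parts in use, the calculation returned 1 and 1.5 there, and 2 and 3.001 over all combinations. The simulated second parts not in use were empty and those in use had equal mean use, unlike in these lists. The simulation therefore checks the arithmetic only. The use of parts, this ratio and its settings were chosen after the lists had been seen.

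Gene identifiers were matched to GENCODE release 29 without their version suffix, and 36366 of 36601 were also in a table of gene names. Positions are 1-based coordinates of that release on GRCh38, the build that the processing notes name. The release is not the annotation behind the lists, and positions are given for matched identifiers. Exons of all transcripts of a gene were merged, and bases shared with exons of another listed gene were counted by strand. Partners were sought only among listed genes matched to release 29, so the 1985 listed genes without a match were not checked. The window at the 3' end was the 500 exonic bases nearest the end of the gene. This overlap count was added after the lists had been seen. Marker genes were compared with the other 19203 listed protein-coding genes by 2-sided Fisher's exact tests, 3 in all, with Benjamini-Hochberg adjustment over the 3.

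The rule for named genes, fixed before the data were examined, took members of the marker lists with no entry or more than 1, of which there were none, and up to 4 members of each list in written order. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen, except partners of a named gene and the pair that belongs to more than 1 list. Alternatives covered how barcodes, shared barcodes, neighbours, composition, genes and markers were counted. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.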

Results

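Single-cell RNA-seq libraries were prepared from 3-dimensional human neural cultures of 2 kinds after 80 days in vitro, with 2 libraries of each. Striatal organoids model the striatum, the forebrain region whose medium spiny neurons are lost in Huntington disease. Striato-nigral circuitoids model the striatum together with the substantia nigra, the midbrain region to which many of these neurons project. The titles describe the cells as derived from human induced pluripotent stem cells, whereas the cell line is given as H9, a human embryonic stem cell line. The extraction protocol names day 35 where the titles name day 80. Both conflicts were left open, and the groups were taken from the titles. Cells were captured in droplets with the 10x Genomics 3' chemistry, version 3, with about 5000 cells targeted per sample and at least 750000 reads per cell stated in the protocol.

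The data analysed here were 1 list of cell barcodes and 1 list of genes for each kind of culture. Each barcode list stood for both libraries of its group, and every barcode carried the same suffix, so the libraries could not be separated. Counts of molecules per gene and cell were not analysed here, and the depth of each library is unknown from these lists. No gene was compared in level between circuitoids and organoids, no cell type was called, and no p-value between the conditions was possible. The comparison of circuitoids with organoids therefore covers the genes that could be counted in each, where the marker genes of the striatum and midbrain lie, and the barcodes listed for each group.

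Circuitoids and organoids were counted over the same genes. The 2 gene lists were identical, with 36601 gene identifiers and 36591 symbols. Of the symbols, 10 had 2 identifiers each, among them MATR3, which encodes a nuclear matrix protein, and TBCE, which encodes a tubulin folding cofactor, both chosen after their entries were seen. None of the marker genes fixed for this tissue was among these symbols. Of the identifiers, 34616 (94.6%) were in GENCODE release 29, the GRCh38 annotation used here for positions, and 33411 of them had the same symbol there. The 1985 identifiers without a match all had numbers above the highest in that release.

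The lists covered mainly genes for proteins and long non-coding RNAs. They held 19351 of the 19951 protein-coding genes of release 29, 7507 of 7629 lincRNA genes and 5547 of 5583 antisense genes. Of the 37 mitochondrial genes, 13 were listed, and all 13 were protein-coding. None of the 1879 microRNA, 1909 snRNA and 943 snoRNA genes of that release was listed, and neither were its 58 rRNA genes.

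All 148 marker genes fixed before the data were examined had exactly 1 entry in both lists, and all were protein-coding. They formed 18 lists with 150 memberships, since FOXA2 and LMX1A belong to both the midbrain dopaminergic neuron and the floor plate list. The striatal medium spiny neuron list had all 20 of its members. BCL11B (ENSG00000127152), a transcription factor of these neurons, lies on chromosome 14 at 99169287 to 99271524, on the minus strand. PPP1R1B (ENSG00000131771), which encodes the dopamine-regulated phosphoprotein DARPP-32, lies on chromosome 17 at 39626740 to 39636626, on the plus strand. No exon of another listed gene overlapped the exons of either. FOXP1 (chromosome 3, 70952817 to 71583993) and FOXP2 (chromosome 7, 114086327 to 114693772), forkhead transcription factors, each shared exonic bases with an antisense gene, 57 of 36714 for FOXP1 and 269 of 16152 for FOXP2. In the whole list, 8 of 20 genes had an opposite-strand overlap.

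All 13 midbrain dopaminergic neuron genes were listed. TH (ENSG00000180176), the rate-limiting enzyme of dopamine synthesis, lies on chromosome 11 at 2163929 to 2171877, and SLC6A3 (ENSG00000142319), the dopamine transporter, on chromosome 5 at 1392790 to 1445430, both on the minus strand and both free of exonic overlap with another listed gene. DDC, which converts L-DOPA to dopamine, lies on chromosome 7 at 50458436 to 50565457 and shared 114 of its 3136 exonic bases with an antisense gene. SLC18A2 (ENSG00000165646), the vesicular monoamine transporter, lies on chromosome 10 at 117241073 to 117279430, on the plus strand. It shared 2326 of its 4145 exonic bases (56.1%) with genes on the opposite strand. Most of these, 2157 bases, lay in PDZD8, at 117277274 to 117375467 on the minus strand, and they covered all of the 500 exonic bases nearest the 3' end of SLC18A2, the part of a transcript that a 3' library reads.

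**Figure D1:**
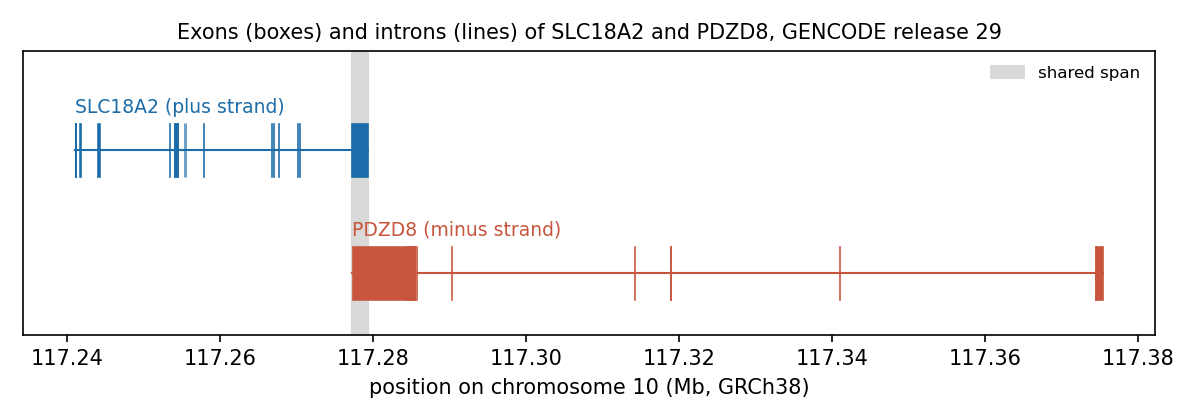
Exons (boxes) and introns (lines) of SLC18A2 on the plus strand and PDZD8 on the minus strand, all annotated transcripts together, by position on chromosome 10 in Mb (GRCh38, GENCODE release 29). The grey band marks the span that both genes cover, where the last exon of SLC18A2 and the last exon of PDZD8 share the 2157 exonic bases that overlap.

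The floor plate list, which describes the midbrain progenitors of dopaminergic neurons, had all 7 members. FOXA2, a forkhead factor of the floor plate, lies on chromosome 20 at 22581005 to 22585455, with no overlap. LMX1A, a LIM homeobox factor on chromosome 1 at 165201867 to 165356715, shared 175 of 4185 exonic bases with an antisense gene. FOXA1 shared 16 of 3982 bases with TTC6. CORIN, a protease used as a floor plate marker, had no overlap.

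Progenitor and GABAergic genes were equally complete. GSX2 (chromosome 4, 54099523 to 54102505), DLX1 (chromosome 2, 172084740 to 172089677) and DLX2 (chromosome 2, 172099439 to 172102900), homeobox genes of the ganglionic eminences, had no exonic overlap. GAD1 and GAD2 encode the enzymes that make GABA, the transmitter of medium spiny neurons. GAD1 shared 468 of 8242 exonic bases with an antisense gene, and GAD2 had no overlap. SLC32A1, the vesicular GABA transporter, had none. Of the 8 radial glia genes, SOX2, HES1 and NES were free of overlap, and VIM shared 1260 of 5158 exonic bases (24.4%) with antisense genes. MKI67, TOP2A, CENPF and BIRC5, genes of dividing cells, had no overlap, nor had the other members of that list of 8.

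Genes tied to Huntington disease and to axon growth were listed as well. HTT (ENSG00000197386), the gene whose repeat expansion causes the disease, lies on chromosome 4 at 3041422 to 3243960 on the plus strand, with 19796 exonic bases and no overlap. BDNF, a neurotrophin that striatal neurons receive from the cortex, shared 701 of 7740 exonic bases (9.06%) with its antisense gene, while its receptor gene NTRK2 and the huntingtin partner gene HAP1 had no overlap. The axon guidance receptors ROBO1 and ROBO2 and their ligands SLIT1 and SLIT2 had no overlap, although 12 of the 25 genes of the axon guidance and synapse list did.

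Lists for other cell types that neural cultures can hold were complete too. Of the 8 medial ganglionic eminence and interneuron genes, NKX2-1 shared 402 of 3165 exonic bases and LHX8 507 of 3977, whereas LHX6 and SST had no overlap. Among the 7 cortical genes, NEUROD6, NEUROD2 and SLC17A7 were free of overlap, and TBR1 shared bases with genes on both strands. GFAP, an astrocyte filament gene on chromosome 17 at 44903161 to 44916937, shared 2230 of 12110 exonic bases with CCDC103 and FAM187A, including all 500 bases nearest its 3' end. ALDH1L1 had 169 such bases in that window, and AQP4 and S100B had none. In the oligodendrocyte list, OLIG1 shared 201 of 2277 bases and SOX10 89 of 3710, with none for OLIG2 and PDGFRA. Of the choroid plexus and cilia genes, FOXJ1 shared 9 of 2641 bases, and TTR, FOLR1 and AQP1 had no overlap. POU5F1, a pluripotency gene, shared 248 of 2896 bases with TCF19, while NANOG, LIN28A and DPPA4 shared none. The mesenchyme list (COL1A1, COL1A2, COL3A1, DCN and another member), the endothelium list (PECAM1, CLDN5, CDH5, FLT1) and the microglia list (AIF1, CX3CR1, P2RY12, CSF1R and another member) had no overlap in any member.

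Over all lists, 45 of 148 marker genes (30.4%) shared exonic bases with a listed gene on the opposite strand and 2 with a listed gene on the same strand. No overlap was found for 102, with the 1985 listed genes outside release 29 not checked. In 9 of the 45 the opposite-strand overlap reached the 500 exonic bases nearest the 3' end. Whether the deposited counting used strand is not given in the sources used here. No reads were examined, so whether reads of such genes were told apart from those of their partners is unknown.

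The barcode lists were far longer than the number of cells targeted. The organoid list held 2036569 barcodes and the circuitoid list 1947405, all distinct and 16 bases long. How the libraries of a group were combined in its list is not given. Taking 2 libraries of about 5000 targeted cells for each list, the lists held 204 and 195 entries per targeted cell. A list entry is therefore not a cell, and the difference of 89164 entries has no replicate check. Every barcode was 1 of 960 first parts of 7 bases followed by 1 of 7078 second parts of 9 bases. These make 6794880 combinations, of which 29.97% were in the organoid list and 28.66% in the circuitoid list.

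Second parts fell into distinct classes of use. They shared 3539 endings of 7 bases, and each ending had 2 second parts whose first pair of bases was complementary. In the organoid list, 3843 second parts were in use, defined as at least 20% of their 960 combinations being listed, and 7076 of 7078 were classed alike in the circuitoid list. For 3235 endings 1 of the 2 second parts was in use, and for 304 both were. Second parts in use by the organoid definition had a median of 52.8% of their combinations listed in organoids (5th to 95th percentile 47.0 to 59.8) and 50.3% in circuitoids (45.0 to 56.8). The medians for the remaining second parts were 2.29% and 2.40%, and these held 82129 and 84785 barcodes.

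**Figure D2:**
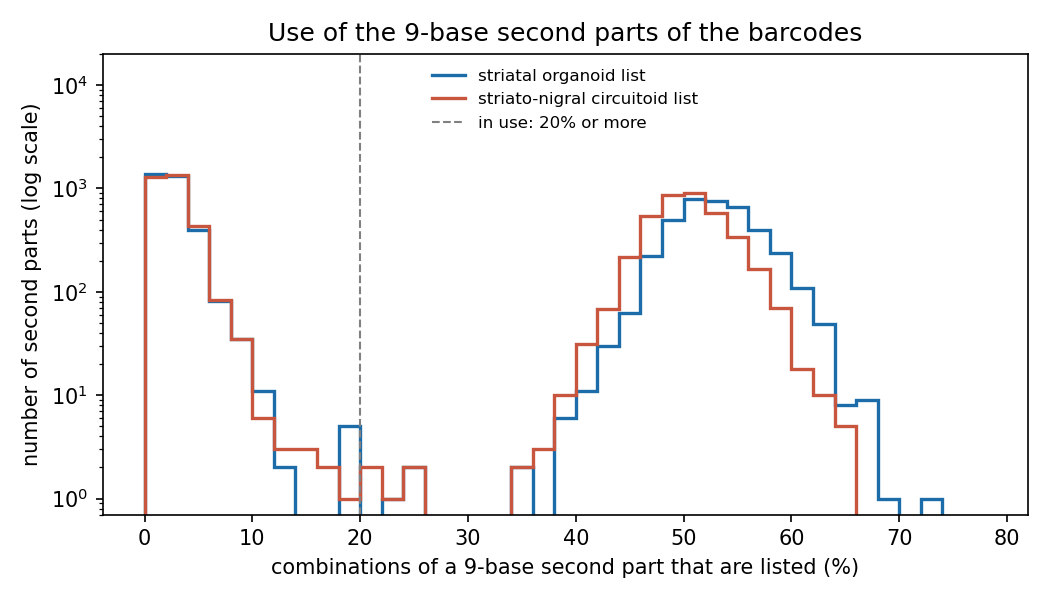
Number of 9-base second parts (log scale) by the percentage of their 960 combinations that were listed, for the organoid and the circuitoid list, each pooling 2 libraries. The dashed line marks 20%, and the medians of the class to its right are 52.8% for organoids and 50.3% for circuitoids.

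Organoids and circuitoids shared 1199992 barcodes, 61.6% of the shorter list (95% Clopper-Pearson interval 61.55 to 61.69) and 58.9% of the longer. Independent draws from all combinations would share 583678, so the overlap was 2.06 ± 0.020 times that number (SD over 100 bootstrap draws of second parts). Among second parts in use the lists shared 1193292 barcodes against 986745 for independent draws, a ratio of 1.21 ± 0.00091. Among second parts not in use they shared 6700 against 2242, a ratio of 2.99 ± 0.076. The split by use of second parts was added after the data were seen. The interval covers counting error only, and the SDs cover spread between second parts. Neither covers spread between cultures, since barcodes are not replicates of a culture.

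Base composition was close in both groups. GC content was 49.66% in organoids (95% interval 49.65 to 49.68) and 49.70% in circuitoids (49.69 to 49.72). The GC intervals count every base as an independent draw, although barcodes are built from shared parts, so they may be too narrow to compare the groups. No base at any position differed between the lists by more than 0.273 percentage points. Barcodes 1 base away from another of the same list made up 4.90% of the organoid list (4.87 to 4.93) and 5.16% of the circuitoid list (5.13 to 5.19), against 22.7% and 21.96% in random draws of the same sizes from all combinations. Among second parts in use these shares were 0.0711% and 0.0668%, against 0.120% and 0.116% in random draws, so most barcodes with a neighbour involved second parts not in use. Neither difference between the groups has a replicate check.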

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

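All settings for the ratio of shared barcodes to independent draws, and both counts of marker overlaps, were chosen after the results were seen; the other settings were fixed before the data were examined. The ratio of 2.06 over all combinations fell to 1.21 among second parts in use and was 2.99 among those not in use. It was also 1.21 with a limit of 10%, with a limit of 30%, with the circuitoid list defining use, and with second parts more than 1 base apart, a setting that removed 8 of 3843. It was 1.203 when the use of each part was kept. The share of shared barcodes, 61.6%, was 43.1% of the union by construction and 60.8% without barcodes 1 base from another. It was 58.9% with both lists at equal size, where fewer organoid barcodes enter. A random draw of organoid barcodes keeps on average the share of the longer list, also 58.9%, so that setting tests nothing. Organoid GC content was 49.60% among barcodes in 1 list, and 4.75% of organoid barcodes had a neighbour at equal list size. The cause of the GC shift was not tested. Circuitoid GC content, gene counts and marker counts moved by less than their intervals or by less than 1.5 times. Equal size leaves the shorter circuitoid list as it is, so its neighbours were not tested. The filter on runs of 6 or more of 1 base removed 0 barcodes and tests nothing. Opposite-strand overlaps of marker genes fell from 45 to 9 in the 3' window, which holds fewer bases. No paired analysis was possible because every barcode carries the same suffix and the libraries cannot be separated. For want of counts, the alternatives on scaling, test, low counts, left-out libraries and genes per cell were not run.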

Other observations

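All tests in this part were chosen after the overlap of the lists and of the marker genes had been seen. For the ratio among second parts more than 1 base apart and the count of shared barcodes with a listed neighbour, the value that would count against the explanation was set before it was computed. The second of these was added after the first had decided nothing.

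Outside the genes named by rule, 6 further marker genes had an opposite-strand overlap within the 500 exonic bases nearest their 3' end, and they are named here because of that value. PAX6, a transcription factor of radial glia, had all 500 bases covered by ELP4. MBP, a myelin protein gene, had 371 bases covered by AC093330.1, and ADORA2A, the adenosine receptor of indirect-pathway medium spiny neurons, had 149 covered by ADORA2A-AS1. The netrin receptor gene DCC had 40, the retinoic acid receptor gene RARB 28 and the synaptic vesicle gene SYN1 23. On the same strand, KCNJ6, a potassium channel gene of dopaminergic neurons, shared 320 exonic bases with DSCR4. KCNJ6 was also chosen after its value was seen. TBR1 shared 385 same-strand bases with SLC4A10 and 226 with AC009487.3. Neither gene had a same-strand overlap within the 500 exonic bases nearest its 3' end.

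Marker genes overlapped other listed genes at rates that were set against those of 19203 other listed protein-coding genes in 3 2-sided Fisher's exact tests. Same-strand overlap was found in 2 of 148 marker genes (1.35%) and in 6.07% of the others, with Fisher's exact p = 0.00896 and 0.0269 after Benjamini-Hochberg adjustment. This argues against a chance difference in rate. It says nothing about a chance choice of genes, since the lists were chosen as markers. Opposite-strand overlap was found in 30.4% and 32.3% (exact p = 0.660, adjusted 0.660). In the 3' window the shares were 6.08% and 11.7%, with an unadjusted Fisher's exact p = 0.0383 that did not pass after adjustment (0.0574). A chance difference in rate therefore stays open for both opposite-strand measures. No biological explanation was tested, and neighbouring genes are not independent.

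Organoid and circuitoid lists shared 2.06 times as many barcodes as independent draws from all combinations. One candidate explanation is unequal use of the 2 complementary second parts of each ending. The first test asked whether keeping second parts in use brings the ratio to at most 5% above 1; it stayed at 1.21 ± 0.00091, which argues against this as the whole cause. The same counts put the excess at 616314 barcodes before and 206547 after, 66.5% less. This drop also leaves out second parts not in use, which shared 6700 barcodes against 2242 for independent draws. An added criterion of more than 50% tests nothing, since its outcome was known when it was set. Independent draws within each class of use would share 986745 barcodes in use and 2242 not in use, against 583678 over all combinations. That rise follows by arithmetic from unequal use of the classes and is no test. What made the use unequal stays open. The beads of this chemistry are known to carry barcodes in pairs that differ at these bases, which was not tested here, and no biological explanation was tested.

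The remaining excess of 206547 barcodes among second parts in use has several candidate explanations. Unequal use of first and second parts is argued against, since keeping it left a ratio of 1.203 ± 0.00088. For single-base read errors, the first test gave 1.21 among second parts more than 1 base apart, but it left out only 8 of 3843 second parts, with 2146 shared barcodes, and so decides nothing. Among all shared barcodes in use, 73988 had a neighbour 1 base away in the same list, a number equal to 35.8% of the excess. This argues against such errors as the source of most of the excess and leaves a smaller part open. The count does not measure how many barcodes such errors made, and no number for chance neighbours was set beside it. Of barcodes on second parts in use, 0.0711% in organoids and 0.0668% in circuitoids had a neighbour on a second part in use. Most of the 73988 therefore had their neighbour on a second part not in use. A bead set holding only part of the combinations stays open and was not tested, since no list of the beads was used here; for independent draws to give this overlap, the set would need to hold 3050703 of the 3689280 combinations in use. Reads carried over between the libraries of the groups could give all 206547 and cannot be told apart from it without counts per barcode, and no biological explanation was tested.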
